A study of Mus musculus with 4 samples.

How the data were processed

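Gene expression was measured on Affymetrix exon arrays in 4 samples of mouse CD4 T cells under TH17-polarising conditions, 2 with 150 nM JQ1 and 2 with DMSO, all labelled 48 hours. The treatment text of the labels also speaks of a stimulation of 4 days, and the 48 hours of the sample titles were taken as the time of the samples. Per the labels' protocols, total RNA was amplified with a whole-transcript kit, labelled with biotin and hybridised. The deposited values are on the log2 scale and, per the submitters' processing notes, come from RMA in Affymetrix Expression Console, which corrects background, quantile-normalizes the arrays and summarises the probes of each row. Versions, settings and the row definition are not given in the sources used here. The same notes name hg19, a human genome build, for mouse samples, so no coordinates are printed.

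The table held 23332 rows and 1 column per sample. Rows were named through a platform annotation table, which gave 1 gene for 14996 rows, several genes for 1019 and no gene for 7317. Entrez identifiers of 14941 of the 14996 rows matched a RefSeq gene table of the mouse assembly GRCm38.p6, which served only for symbols. Genes are named from rows with 1 gene only, and a gene of which only shared or unlisted rows exist was not analysed here. For the 135 genes with several rows, the row with the highest mean over the 4 arrays stood for the gene, giving 14860 genes. No filter on dim genes was used for the reported tests. The deposited values carry no detection calls. A background reference was therefore taken from 800 olfactory and vomeronasal receptor genes, whose means had a median of 3.61 and a 95th percentile of 5.80, and this choice was made after the data were seen.

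Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, JQ1 against DMSO, 2 residual degrees of freedom and 3.43 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A change is the log2 value with JQ1 minus that with DMSO, its SE is limma's moderated one, its interval is at 95%, and a fold is 2 to the power of the change. For 37 gene lists fixed in advance, members were also adjusted over the list alone, and 36 lists were tested with camera at a preset correlation of 0.01, with adjustment over the lists. The list of mitochondrially encoded transcripts had no row and was not analysed here. The 2 TH17 lists were set against the TH1, TH2, regulatory T cell and follicular helper lists with cameraPR, and adjusting over these 2 tests was decided after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

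The genes named in the text follow a rule written before the data were examined. It takes the 10 largest rises and falls past the threshold, filled up with the smallest unadjusted p in that direction, without symbols of predicted genes, olfactory and vomeronasal receptors and small RNAs. It adds 25 genes of TH17 biology, other helper lineages and BET proteins whatever their values, of which some are not reported here, and from each list up to 4 members past the test over the list alone or, where none passed, up to 2 with the largest change. All members past the test are named for the TH17 cytokine and pathogenic lists, and further genes are named beside the brighter genes, in both cases chosen after their values were seen.

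The scripts were tested on 20 simulated data sets with the genes and spread of the comparison of JQ1 with DMSO, 14860 genes each. The gene test called 11.3% of genes changed by 1 log2 unit, 86.4% of those changed by 2, 96.4% of those changed by 3 and 0.0396% of unchanged genes. The 20 sets together held 1340, 1340 and 1320 genes with these 3 changes, and the spread was drawn without regard to brightness. The share called after Benjamini-Hochberg adjustment depends on how many genes change. In the real fit Il17f, at -3.41, did not pass (limma adjusted p = 0.0901), so these rates do not carry over to the real data. Camera called a shifted list in 20 of 20 sets and 1 of 800 unshifted lists. The simulated genes varied independently, while members of real lists can vary together (estimated correlation 0.547 for G2/M and mitosis). These rates of camera therefore do not carry over to such lists.

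Alternatives written in advance were limma with a variance trend or a robust prior, a further quantile normalization, centring on the median, filters at the median and the 25th percentile of brightness, the mean of all rows of a gene, every row tested alone, the replicate number as a block, each array left out, other thresholds, camera with an estimated correlation or on ranks, fry, and a preset correlation of 0.05. Cyclic loess, adjustment over the 439 genes of all lists, 10000 random lists matched on brightness, and the filter at the median of brightness combined with each scaling or with 1 array left out were added after the data were seen. Where an array was left out, the lone array of its group was assumed to vary like the other group. No scan date or batch was used here.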

Results

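The series measured the effect of JQ1, a small molecule that occupies the acetyl-lysine pockets of the BET bromodomain proteins and so displaces them from chromatin, on mouse CD4 T cells kept under conditions that favour TH17 cells, the helper T cells that make IL-17. Naive CD4 T cells from the spleens of C57BL/6 mice, over 90% pure per the labels, were stimulated through CD3 and CD28 with TGF-β1, IL-6, IL-23 and antibodies against IFN-γ and IL-4. They received 150 nM JQ1 or its solvent DMSO for 48 hours. RNA from 2 samples with JQ1 and 2 with DMSO was read on Affymetrix exon arrays, giving 4 arrays with 1 log2 value per row and 14860 named genes. No label says whether the replicates came from separate mice or cultures, so the p-values of single genes measure the spread between these samples, which may be technical. The list tests camera and cameraPR at a preset correlation set genes against genes and take them as almost independent. Their p-values therefore measure the spread among genes and not that between samples. The number of arrays limits the precision, and an exact permutation test of 2 arrays against 2 cannot go below p = 0.333.

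Across the 14860 genes, Pearson r was 0.981 between the DMSO arrays and 0.982 between the JQ1 arrays. Between a DMSO and a JQ1 array r ranged from 0.976 to 0.980. Among the brighter genes (above the median mean signal), r was 0.973 and 0.974 within groups and 0.953 to 0.964 between groups. Over all 23332 rows it was 0.949 and 0.952 within groups and 0.943 to 0.952 between groups, and the pair with the highest r there was DMSO replicate 2 with JQ1 replicate 2. Genes are not independent replicates, and these values only describe the arrays. No pair of arrays held the same values.

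The comparison of JQ1 with DMSO asks which transcripts change in TH17-polarised cells when BET bromodomains are occupied. Granzyme B (Gzmb, Entrez gene 14939), a protease of cytotoxic granules, fell 10.7-fold, from a log2 signal of 7.47 ± 0.16 (SD, n = 2) with DMSO to 4.05 ± 0.00066 with JQ1. It was the 1 gene of 14860 that passed limma's moderated test after Benjamini-Hochberg adjustment over all genes (log2 change -3.42, SE 0.16, adjusted p = 0.0238), and no gene passed as higher. At an unadjusted p below 0.05 the limma fit held 1483 genes, 1228 lower and 255 higher with JQ1, where 743 would be there by chance. The call of Gzmb was lost whichever array was left out, in fits with a lone array in 1 group. Its log2 change there stayed between -3.53 and -3.30, so the loss does not show that the fall rests on a single array. The Gzmb signal with JQ1 also lay below 5.80, the 95th percentile of 800 olfactory and vomeronasal receptor genes, which served as a background reference chosen after the values were seen.

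The 9 genes that followed Gzmb by unadjusted p in that direction did not pass over all genes, with limma adjusted p from 0.0901 to 0.175. Among them, Il17f, which encodes the cytokine IL-17F (Entrez gene 257630), had a log2 change of -3.41 (SE 0.24), a 10.6-fold lower signal, from 11.34 ± 0.24 with DMSO to 7.93 ± 0.40 with JQ1. The calcium-binding protein gene S100a6 had a log2 change of -2.54 (SE 0.18), and Cd86, a co-stimulatory ligand, -2.22 (SE 0.17). The chemokine receptor gene Ccr6 was at -2.68 (SE 0.27), the interleukin 1 receptor gene Il1r1 at -1.78 (SE 0.19) and the cytokine gene Il9 at -1.54 (SE 0.14). Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, was at -1.64 (SE 0.15), Gatm, an enzyme of creatine synthesis, at -1.94 (SE 0.19), and the deaminase Rida at -1.57 (SE 0.15). The means of Cd86 and Gatm with JQ1 lay under the background reference.

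None of the 10 genes with the smallest unadjusted p among those higher with JQ1 passed over all genes (limma adjusted p from 0.212 to 0.280). The brightest was Zfp36l1, an RNA-binding protein that speeds mRNA decay, with a log2 change of 0.76 (SE 0.14) and a level of 9.79 ± 0.018 with DMSO and 10.55 ± 0.056 with JQ1 (SD, n = 2). Tbrg3 was at 0.96, Ccdc115 at 1.03, the glycogen branching enzyme Gbe1 at 0.74 and the collagen gene Col10a1 at 0.79. The other 5, Hacd1 (1.23), Mbd3l1 (1.25), the transcription factor Mef2d (2.84), AF366264 (0.97) and Mab21l2 (1.56), had a DMSO mean under the background reference of 5.80, and the JQ1 means of these other than Mab21l2 were under it too.

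The changes leaned to the lower side, by a margin that moved with the scaling of the arrays. The median change of all genes was -0.09, and 82.8% of the genes at an unadjusted p below 0.05 were lower with JQ1. After a further quantile normalization that share was 74.2% (991 lower, 345 higher), and after centring each array on the median of its named genes, which moved the median change to 0.03, it was 54.3% (679 lower, 572 higher). Cyclic loess between the arrays, added after the data were seen, gave 59.6% (805 lower, 545 higher). Changes of at least 2-fold were counted for 151 genes lower and 42 higher in the deposited values, and for 95 and 63 after centring. Of the 151 and 42, 108 and 9 had a mean above the background reference of 5.80 in at least 1 group. A change given below is 0.09 less negative when taken relative to the median of all genes, while the mean shifts of gene lists are already relative to the other genes. The median change moved with brightness, from 0.0014 for genes with a mean up to 4 to -0.20 above 9. For bright genes the offset was therefore larger, and after cyclic loess Myc went from -0.43 to -0.23 and Thy1 from -0.71 to -0.51.

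**Figure D1:**
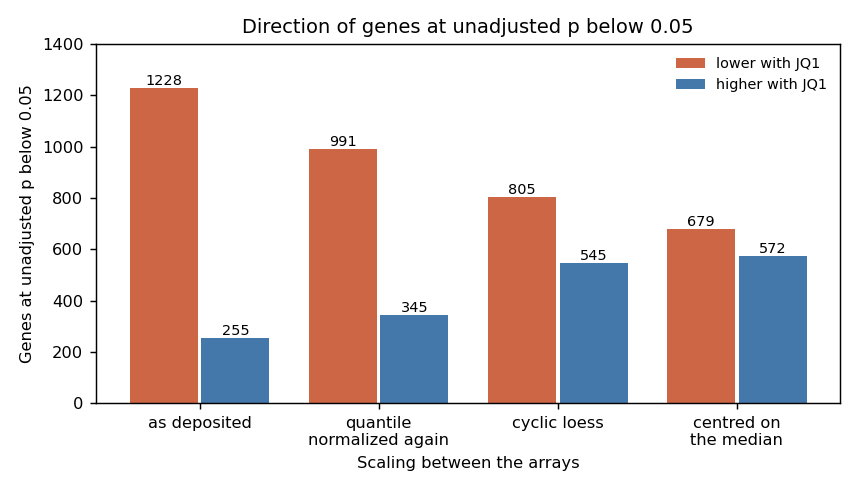
Number of genes at an unadjusted p below 0.05 (vertical axis, limma, 14860 genes) that were lower or higher with JQ1, under 4 scalings between the arrays (horizontal axis). The bars run from 1228 lower and 255 higher as deposited to 679 lower and 572 higher after centring on the median.

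The genes of the TH17 cytokine and receptor list, not all of which are particular to TH17 cells, fell together with JQ1. All 11 measured members of this list, which was fixed before the data were examined, were lower on both JQ1 arrays than on both DMSO arrays, and all 11 passed limma's test when adjusted over the list alone, 6 when adjusted over the 439 genes of all lists, and 0 over all 14860 genes (11 at an unadjusted p below 0.05). Il17f fell most, followed by Ccr6 (6.40-fold), the receptor for CCL20, Il1r1 (3.43-fold) and Il9 (2.91-fold). Il17a, which encodes IL-17A, fell 2.59-fold (log2 change -1.37, SE 0.16), from 7.16 ± 0.11 to 5.79 ± 0.16 (SD, n = 2), Il10 fell 2.58-fold, and the IL-23 receptor gene Il23r fell 2.36-fold. The GM-CSF gene Csf2 fell 2.32-fold. Il21 (1.61-fold), Ccl20 (1.6-fold) and Il12rb1 (1.41-fold) fell least. The means of Il17a, Csf2, Il23r and Ccl20 with JQ1 lay at or under the background reference of 5.80, and those of Csf2 and Il23r with DMSO did too. Il22 was not analysed here. In all, 16 listed genes passed over the 439 genes, all lower. They were Il17f, Ccr6, Il1r1, Il9, Il17a, Il23r, Gzmb, Il2, Il7r, Il24, Klrd1, Pou2af1, Cxcr4, Xcl1, Rora and Fdft1. In the fit as reported, other genes described below as past the test over their list alone did not pass over these 439 genes.

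The list's mean change was 1.39 log2 units below that of all other genes, with a median of -1.37. The competitive test camera at a preset correlation of 0.01 gave an adjusted p of 3.77e-15 over 36 lists. The call was lost with an estimated correlation (adjusted p = 0.465 with an estimated correlation). That test rests on the 2 residual degrees of freedom and called none of the 36 lists, so a loss there does not tell the lists apart. With the self-contained test fry the lists called were this one, the pathogenic TH17 list and the cytotoxic granule list (adjusted p = 0.0486 each), so the other lists described below as called were not called by fry. None of 10000 random lists matched on brightness had a median as low. Random lists ignore co-expression among members, and the same held for the pathogenic, chemokine and G2/M lists. For the TH1 list, which camera did not call, 4 of the 10000 were as low, so this result does not set the TH17 list apart. Leaving out any 1 array left 9 to 11 members past the test over the list alone, and the members lost were Il12rb1 and Ccl20.

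**Figure D2:**
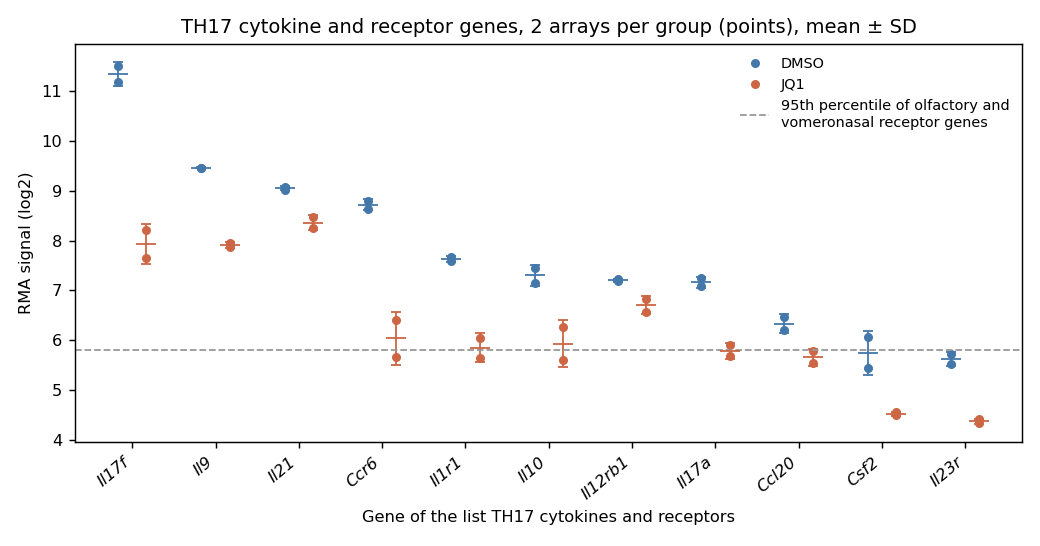
Log2 RMA signal (vertical axis) of the 11 measured TH17 cytokine and receptor genes (horizontal axis), with points for the 2 arrays of each group, horizontal ticks for the group means and bars for the SD. The dashed line is the background reference of 5.80, and each JQ1 mean lies below its DMSO mean, from 11.34 against 7.93 for Il17f to 5.62 against 4.38 for Il23r.

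Among 13 measured transcription factor genes of TH17 cells, 3 fell when adjusted over the list alone and none over all genes in the limma fit (5 at an unadjusted p below 0.05, all lower). These were Rora, a nuclear receptor that drives TH17 differentiation (1.78-fold, log2 change -0.83, SE 0.15), Ahr, the aryl hydrocarbon receptor (1.67-fold), and Batf, an AP-1 family factor (1.66-fold). Irf4 had a log2 change of -0.16 (SE 0.17) and Stat3, the factor activated by IL-6 and IL-23, -0.07 (SE 0.14), with an interval from -0.42 to 0.29. Both signs depended on the scaling, since Stat3 was at 0.05 after centring, 0.07 after quantile normalization and 0.12 after cyclic loess, and Irf4 at 0.05 after cyclic loess. The list's mean change was 0.20 below that of other genes (camera adjusted p = 0.0379, and adjusted p = 0.656 with an estimated correlation). The list's call was lost with camera on ranks (0.101), after quantile normalization (0.140) and cyclic loess (0.112), among genes above the median (0.105) or the 25th percentile (0.0680) of brightness and without DMSO replicate 1 (0.0860), DMSO replicate 2 (0.163) or JQ1 replicate 1 (0.165), and leaving out any 1 array left 0 members past the test. After quantile normalization or cyclic loess 0 members were past it, and after centring 1, Rora. Maf was not analysed here.

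Genes linked to pathogenic TH17 cells were called lower as a list over all genes, a call lost among genes above the median brightness and with an estimated correlation (adjusted p = 0.598 with an estimated correlation). Of 14 measured, 6 fell when adjusted over the list alone, and Gzmb also over all genes. After Gzmb came Csf2, the chemokine gene Ccl3 (2.06-fold, log2 change -1.04, SE 0.26) and the kinase gene Sgk1 (1.76-fold), and the remaining pair were Il3 and Lgals3. The means of Gzmb, Csf2, Sgk1 and Il3 with JQ1 lay under the background reference, and those of Csf2 and Il3 with DMSO did too. Lag3, an inhibitory receptor gene, passed over this list alone as higher after each of the 3 scalings, with either filter on brightness and with a variance trend. The list's mean change was 0.57 below that of other genes (camera adjusted p = 0.000453), and above the median brightness it was 0.22 below (adjusted p = 0.297). The number of lower members past the test was 3 above the median brightness, 4 without DMSO replicate 1, 3 without DMSO replicate 2, and 1 without either JQ1 replicate.

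Of 8 measured genes of cytotoxic granules, Gzmb and Nkg7 (1.85-fold, log2 change -0.88, SE 0.17) fell when adjusted over the list alone, and the list as a whole was not called by camera (adjusted p = 0.133). It was called above the 25th percentile of brightness (adjusted p = 0.00474, mean shift -0.91 against -0.48) and by fry. Cd8a, 1 of 3 measured markers of CD8 T cells, fell 1.66-fold (log2 change -0.73, SE 0.20), and Klrd1, a receptor subunit of natural killer cells, fell 3.31-fold (log2 change -1.73, SE 0.25), each adjusted over its own list alone and with a JQ1 mean under the background reference. The 5 measured natural killer markers did not shift as a list (median -0.09, camera adjusted p = 0.665). The call of Cd8a was lost after centring, after cyclic loess and without either DMSO replicate or JQ1 replicate 1, and that of Nkg7 without DMSO replicate 1 or JQ1 replicate 1.

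Among the genes of other helper lineages, those of follicular helper cells were called as a list (camera adjusted p = 0.000906, and adjusted p = 0.656 with an estimated correlation), and 4 of 9 fell when adjusted over the list alone. These were the chemokine receptor gene Cxcr5 (4.61-fold, log2 change -2.21, SE 0.42), the transcriptional coactivator gene Pou2af1 (2.55-fold), Slamf6 (1.64-fold) and Bcl6, the lineage's master regulator (1.45-fold). The mean of Cxcr5 with JQ1 lay under the background reference. Their mean change was 0.58 below that of other genes, and 2 members were past the test after centring, after cyclic loess, or without DMSO replicate 1 or either JQ1 replicate. Of 10 TH2 genes, the chemokine receptor gene Ccr3 (2.0-fold) and the cytokine gene Il24 (1.95-fold) fell, both at means under the background reference, and of 11 regulatory T cell genes, Ebi3 (1.94-fold) and Entpd1 (1.78-fold) fell, both to JQ1 means under it. No TH1 gene of 11 passed adjusted over the list alone in limma (3 at an unadjusted p below 0.05, all lower), and Il12rb2 was at -0.81 (SE 0.25), with both means under the background reference. Among genes above the 25th percentile of brightness Il12rb2, Il18r1 and Runx3 passed as lower, and above the median Runx3 did. The camera adjusted p was 0.103 for TH1, 0.161 for TH2 and 0.154 for regulatory T cell genes, and leaving out JQ1 replicate 1 took the TH1 list to 0.0127. Without DMSO replicate 1 or JQ1 replicate 1 no TH2 gene passed, and no regulatory T cell gene did after centring, after cyclic loess or without either DMSO replicate or JQ1 replicate 2.

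Single genes of these lineages spread widely between replicates or changed little. Ifng had a log2 change of -0.70 (SE 0.46), with DMSO arrays at 7.11 and 6.16 and JQ1 arrays at 6.47 and 5.40. Il4 was at -0.57 (SE 0.25), Gata3, the TH2 regulator, at 0.33 (SE 0.18) and Tbx21, the TH1 regulator, at 0.04 (SE 0.14), and none of them passed the test. With the replicate number as a block, a pairing that no label gives, Ifng passed over the TH1 list alone as lower. With 1 array left out, Ifng ranged from -1.23 to -0.16 and Il4 from -0.91 to -0.22, and without DMSO replicate 2 Il4 passed over the TH2 list alone as lower. Foxp3 was not analysed here.

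Set directly against the 41 measured genes of the TH1, TH2, regulatory T cell and follicular helper lists, the 11 TH17 cytokine and receptor genes were lower by 1.09 log2 units (means of -1.50 and -0.41, two-sided limma cameraPR at a preset correlation of 0.01, adjusted p = 4.62e-08 over the 2 TH17 lists). That p-value measures the spread among these genes, taken as almost independent, and not the spread between samples. The 13 TH17 transcription factor genes did not differ detectably from these 41 genes (difference 0.10, limma cameraPR adjusted p = 0.979).

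**Figure D3:**
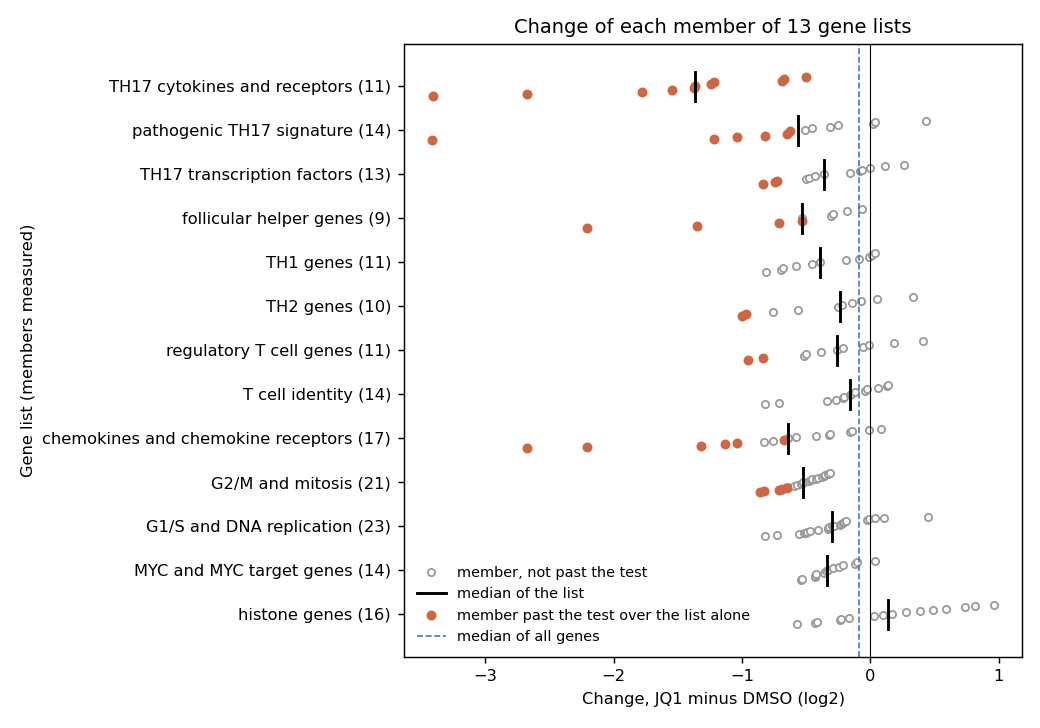
Log2 change, JQ1 minus DMSO (horizontal axis), of each measured member of 13 gene lists (vertical axis), with filled points for members past limma's test adjusted over the list alone, black bars for list medians and a dashed line for the median of all genes at -0.09. The median of the TH17 cytokine and receptor list lies at -1.37 and that of the T cell identity list at -0.16.

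Chemokine and chemokine receptor genes were called lower as a list, a call lost with an estimated correlation (adjusted p = 0.598 with an estimated correlation). Of 17 measured, 6 fell when adjusted over the list alone, led by Ccr6, Cxcr5 (with a JQ1 mean under the background reference), Cxcr4, the receptor for CXCL12 (2.50-fold, log2 change -1.32, SE 0.21), and the chemokine gene Xcl1 (2.19-fold). Their mean change was 0.67 below that of other genes (camera adjusted p = 5.89e-06). Without DMSO replicate 1 the call of Cxcr5 was lost. Ccr6 and Ccl20 are shared with the TH17 list, Cxcr5 with the follicular helper list and Ccl3 with the pathogenic list, which also shares Csf2 with the TH17 list, so these lists are not separate observations.

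Genes of T cell activation and of the naive state did not shift as groups (camera adjusted p = 0.933 over 16 genes and 0.916 over 13), yet each held 1 gene that fell. Il2, the T cell growth factor gene, fell 3.19-fold (log2 change -1.67, SE 0.20), and Il7r, the IL-7 receptor subunit gene of resting T cells, fell 3.19-fold (log2 change -1.68, SE 0.28), each adjusted over its list alone. Cd40lg passed over the activation list alone as higher with a variance trend, after centring, after cyclic loess and with either filter on brightness. Il2 was past the test whichever array was left out, and Il7r was not past it without DMSO replicate 1 or JQ1 replicate 1. The mean of Il7r with JQ1 lay under the background reference. Of 8 co-inhibitory receptor genes none passed in limma (1 lower and 1 higher at an unadjusted p below 0.05), with Btla at -0.53 (SE 0.18) and Lag3 at 0.44 (SE 0.15).

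Genes of G2/M and mitosis were lower as a list, a call lost with an estimated correlation (adjusted p = 0.656 with an estimated correlation). All 21 measured genes of G2/M and mitosis had a negative change, and 5 fell when adjusted over the list alone, including the mitotic regulators Cdc20 (1.81-fold), Aurka (1.78-fold), Nusap1 (1.64-fold) and Hmmr (1.62-fold). None of the 21 passed when adjusted over the 439 genes of all lists. The list's mean change was 0.43 below that of other genes (camera adjusted p = 5.12e-09). The number of members past the test was 0 after centring, quantile normalization or cyclic loess and without DMSO replicate 1 or JQ1 replicate 1, 1 without DMSO replicate 2, 8 above the 25th percentile of brightness, and 10 with a variance trend, above the median brightness or without JQ1 replicate 2.

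Of 23 genes of G1/S and DNA replication none passed adjusted over the list alone in limma (5 at an unadjusted p below 0.05, all lower), with the replication helicase gene Mcm3 at -0.82 (SE 0.19) and the cyclin gene Ccne2 at -0.73 (SE 0.14), both of which passed with a variance trend and with either filter on brightness. Their mean change was 0.18 below that of other genes (camera adjusted p = 0.00682, and adjusted p = 0.657 with an estimated correlation), a call lost above the median brightness (0.0679) and without DMSO replicate 2 (0.158) or JQ1 replicate 1 (0.137). Of the 14 measured genes of the MYC list, Myc included, none passed in limma (4 at an unadjusted p below 0.05, all lower). Myc, a gene often repressed by BET inhibitors, had a log2 change of -0.43 (SE 0.14), Srm, an enzyme of polyamine synthesis, -0.54 (SE 0.15), and Nme1 -0.53 (SE 0.18). The list's mean change was 0.20 below that of other genes (camera adjusted p = 0.00703, and adjusted p = 0.656 with an estimated correlation), a call lost after quantile normalization (0.0785), after cyclic loess (0.0616), above the median brightness (0.0596) and without DMSO replicate 1 (0.0860) or JQ1 replicate 1 (0.137).

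Histone genes were the 1 list called higher with JQ1, by 0.26 over other genes on 16 measured members (camera adjusted p = 0.0202, and adjusted p = 0.656 with an estimated correlation). None of the 16 passed alone in limma (2 at an unadjusted p below 0.05, both higher), and the largest change, 0.97 for H1f1 (SE 0.79), came from DMSO arrays at 4.33 and 6.88. H2ac6 was at 0.82 (SE 0.66), with both means under the background reference. H1f2 passed over the list alone as higher after each of the 3 scalings and with either filter on brightness, H2aw in these except after centring, and H1f1 without DMSO replicate 2. The list's call was lost with camera on ranks (0.0803), after centring (0.0894), quantile normalization (0.128) and cyclic loess (0.195) and without DMSO replicate 1 (0.260) or JQ1 replicate 2 (0.210).

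The BET proteins themselves and the regulators of P-TEFb, the kinase that releases paused RNA polymerase II, did not move as a group (11 genes, camera adjusted p = 0.547). Hexim1, an inhibitor of P-TEFb whose transcript is a common readout of BET inhibition, had a log2 change of 0.58 (SE 0.21), and it did not pass adjusted over the list alone in limma, although it was the 1 member at an unadjusted p below 0.05. Brd2 was at 0.26 (SE 0.18), Brd3 at -0.32 (SE 0.14) and Larp7 at -0.49 (SE 0.24). Larp7 had a dimmer row as well, which gave 0.18.

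Other growth, survival and metabolism lists were not called by camera. The adjusted p was 0.346 for 25 genes of ribosome biogenesis (Nolc1 at -0.47 and Mrto4 at 0.45), 0.551 for 21 cytosolic ribosomal protein genes (Rps15 at -0.71 and Rpl35a at -0.54) and 0.464 for 9 cell cycle inhibitors (Cdkn1a at -0.48 and Cdkn2c at -0.34). It was 0.551 for 12 p53 target genes (Cdkn1a and Sesn2, the latter at -0.44), 0.665 for 14 genes of the BCL2 family and death ligands (Bad at -0.54 and Bid at -0.41) and 0.161 for 12 glycolysis genes (Tpi1 at -0.83 and Slc16a3 at -0.79). No member of these 6 lists passed adjusted over its list alone in limma, with 9 lower and 0 higher at an unadjusted p below 0.05, Cdkn1a being counted in 2 lists. With a variance trend Cdkn1a passed as lower over the cell cycle inhibitor list, and Tpi1 passed as lower over its list there and with either filter on brightness. The means of Rps15 lay under the background reference in both groups, and that of Bid with JQ1 did. Among 16 genes of cholesterol synthesis (camera adjusted p = 0.231), Fdft1, which makes squalene, fell 1.78-fold (log2 change -0.83, SE 0.14), a call lost after centring, quantile normalization and cyclic loess and whichever array was left out.

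Signalling and stress lists held few changes. Among 13 genes of STAT3 and cytokine signalling (camera adjusted p = 0.153), the cytokine gene Lif fell 2.09-fold (log2 change -1.06, SE 0.19) while the list's mean lay 0.12 above that of other genes. That list was called higher after quantile normalization (0.0170) and cyclic loess (0.0264), where Cish and Socs2 passed over the list alone as higher, and Lif was lost whichever array was left out. Among 8 genes of heat shock and immediate early stress (camera adjusted p = 0.458), the early response gene Ier3 rose 1.84-fold (log2 change 0.88, SE 0.20), a call lost without DMSO replicate 1 or either JQ1 replicate. Hspa1a of the same list passed as higher with a variance trend, after each of the 3 scalings, with either filter on brightness and without JQ1 replicate 1. The median of that list was -0.11 although its mean lay 0.19 above other genes. No member passed in limma among 17 interferon response genes (Bst2 at -0.95 and Gbp3 at -0.90), 12 NF-κB genes (Cd83 at -0.74 and Traf1 at -0.46), 14 TGF-β response genes (Tgfbr1 at -0.59 and Tgif1 at -0.55) or 16 genes of the unfolded protein and amino acid response (Asns at -1.0 and Xbp1 at -0.53). These 4 lists had camera adjusted p of 0.689, 0.551, 0.231 and 0.464, and 7 lower and 0 higher members at an unadjusted p below 0.05. Without JQ1 replicate 2 Bst2, Gbp2 and Gbp3 passed as lower, Bst2 also with a variance trend and either filter on brightness, and Asns passed as lower with either filter. The means of Cd83 lay under the background reference in both groups, and that of Gbp3 with JQ1 did.

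Among the markers of cell type, Cd8a and Klrd1 were the genes past limma's test adjusted over a list alone. The 14 genes of T cell identity had a median change of -0.16 (camera adjusted p = 0.464) and none passed in limma (2 at an unadjusted p below 0.05, both lower), with Ubash3a at -0.82 (SE 0.26) and Thy1 at -0.71 (SE 0.21), and Ubash3a passed as lower without JQ1 replicate 2. The CD8 list of 3 genes had a camera adjusted p of 0.0624, which was 0.0336 after centring, 0.0481 after cyclic loess and 0.0392 without JQ1 replicate 2, and the natural killer list of 5 genes had 0.665. None of 11 B cell genes passed in limma (0 at an unadjusted p below 0.05), with Cd79b at -0.63 and Cd79a at -0.34, and none of 8 erythroid and platelet genes did either (0 at an unadjusted p below 0.05), with Gp9 at -0.49 and Pf4 at 0.24. The camera adjusted p was 0.916 and 0.551 for these lists, and the JQ1 means of the 4 genes named from them lay under the background reference. Among 12 myeloid genes (camera adjusted p = 0.420, 1 higher at an unadjusted p below 0.05), the neutrophil genes S100a9 and S100a8 had changes of 1.86 (SE 0.65) and 1.19 (SE 0.60) and did not pass. Their DMSO arrays lay far apart, at 5.89 and 7.88 for S100a9 and 4.66 and 6.30 for S100a8, and without DMSO replicate 2 both passed as higher.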

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

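The tests of this part were chosen before their results were seen. The rows concerned lie outside the comparisons of named genes, and the histone row below was picked for its large rise. Of the 7317 rows without a gene name, 144 were higher with JQ1 by over 2 log2 units and 24 were lower, a signal in rows not used for the named genes. Of the 14996 rows with a single gene, 1 was that much higher and 12 were that much lower. A spread between arrays that has nothing to do with JQ1 is a candidate explanation, since 131 such rows were counted when the arrays numbered 1 were set against those numbered 2, against 168 for JQ1 against DMSO and 113 for the remaining split, and the lean to 1 side was there too (110 and 21, and 77 and 36). The count for the real split was above both others, by a margin that 3 splits cannot test, so the spread between arrays and JQ1 cannot be told apart for these rows. A biological explanation, namely transcripts without a gene name that rise with JQ1, stays open and was not tested.

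A row shared by 9 histone H2A genes was higher with JQ1 by 3.20 log2 units, from 2.13 with DMSO to 5.33 with JQ1 (limma unadjusted p = 0.00393). It was picked as the largest rise among the 15 rows shared by 5 or more histone genes, so this p-value follows a selection on the same values. Another row listing the same 9 genes differed by 0.32, and the means of both rows lay under the background reference of 5.80 in both groups. Over 15 rows shared by 5 or more histone genes, 11 were higher with JQ1, the median change was 0.30, and at an unadjusted p below 0.05 (limma) 2 were higher and 1 was lower. No explanation was tested for these rows.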

How the results depend on the processing

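Cyclic loess and the adjustment over the genes of all lists were chosen after the data were seen. Signal over background limits the dim genes and 2 arrays per group limit all tests. With 1 gene past the test over all genes, the count was 3 (all lower) at an adjusted p below 0.10 and 3 with a variance trend, 50 among genes above the median brightness and 9 above its 25th percentile (all lower), where fewer genes are tested, and 0 when every row was tested alone and whichever array was left out. It was 1, and the gene was Gzmb, after centring, quantile normalization and cyclic loess. The adjusted p of Gzmb ranged from 0.00337 to 0.355 over the alternatives that tested it. The listed genes past the test over all listed genes, 16 as reported, numbered 32 with a variance trend, 31 and 39 with the filters, and 2 to 6 with 1 array left out.

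The number of lists called was 9 (8 lower, 1 higher). It was 0 lower and 0 higher with an estimated correlation, a test that rests on the 2 residual degrees of freedom, and the TH17 cytokine shift of -1.39 then had an adjusted p of 0.465 at an estimated correlation of -0.0482. It was 3 lower and 0 higher with fry, 7 lower and 0 higher on ranks, 9 lower and 0 higher after centring, and 5 in all with 4 lower among genes above the median brightness. With 1 array left out it was 6 to 9, with 0 to 1 higher. The TH17 cytokine list was called lower in every fit except that with an estimated correlation, and its members past the test numbered 6 after adjustment over all listed genes and 8 to 11 elsewhere. Its difference from the other helper lists was -1.35 to -1.03 throughout. The difference of the TH17 transcription factors turned to -0.0086 above the median brightness. The causes were not tested.

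No label says that the replicate numbers pair the arrays, and they were not taken as pairs. The deviations of same-numbered arrays had a correlation of 0.0967 over genes, which with 2 pairs does not settle whether they do. With the replicate number as a block, 0 genes passed (Gzmb adjusted p = 0.178), 10 listed genes passed over all listed genes, and 10 lists were called, 9 of them lower, with the TH1 and CD8 lists added and the TH17 transcription factor list not among them. Over their lists alone, Ifng, Il12rb2, Il18r1, Ccr2, Cxcr6, Tpi1 and Slc16a3 were then added as lower and Hspa1a as higher. Batf, Lgals3, Ebi3, Bcl6, Il7r, Fdft1 and Lif no longer passed.

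Some values changed sign, none of them past a test where its sign had changed, and the cause was not tested. After quantile normalization these were the mean shifts of the lists for the naive state (0.038), activation (0.010), ribosome biogenesis (0.018), the BCL2 family (0.0039), NF-κB (0.0012) and B cells (-0.036), and Stat3 (0.071). After centring it was Stat3 (0.049). After cyclic loess these were the lists for the naive state (0.025), activation (0.0070), ribosome biogenesis (0.015) and B cells (-0.025), with Irf4 (0.046) and Stat3 (0.12). Above the median brightness these were the lists for regulatory T cells (0.045), the BCL2 family (0.051) and NF-κB (0.041), and above the 25th percentile that for B cells (-0.17). With 1 array left out, shifts ranged from -0.14 to 0.055 for the naive list, -0.12 to 0.024 for activation, -0.013 to 0.17 for BET proteins, -0.076 to 0.027 for the BCL2 family, -0.079 to 0.14 for ribosomal proteins and -0.12 to 0.12 for B cells. They ranged from -0.059 to 0.063 for co-inhibitory receptors, -0.13 to 0.034 for p53 targets, -0.033 to 0.15 for erythroid genes and -0.11 to 0.019 for ribosome biogenesis, and H1f1, which passed over its list alone without DMSO replicate 2, from -0.31 to 2.24. Over all alternatives together, list shifts lost their call 40 times and gained one 10 times, and changes of named genes lost it 5 times and gained it 24 times. Every alternative written in advance was run.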

Other observations

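The test of the T cell share, the cyclic loess, the brighter genes under other scalings or without an array, and the demand that the interval of a share lie on 1 side of 60% were chosen after the results were seen. Among the 7430 genes above the median brightness 50 genes passed limma's test and all 50 were lower with JQ1, of which 40 belong to no list. The genes named here were chosen after their values were seen. Pdpn, which encodes the membrane glycoprotein podoplanin, fell 6.13-fold (log2 change -2.62, SE 0.39), Timp1, an inhibitor of matrix metalloproteinases, 4.53-fold (-2.18, SE 0.24), and Cd80, a co-stimulatory ligand like Cd86, 3.41-fold (-1.77, SE 0.25). Inhba, a subunit of the TGF-β family ligand activin A, fell 3.18-fold, the receptor tyrosine kinase gene Axl 2.35-fold, and the membrane protein genes Tmem176a and Tmem176b 2.72-fold and 2.81-fold. The means of Cd80, Tmem176a and Tmem176b with JQ1 lay under the background reference of 5.80.

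Egln3, an oxygen-dependent prolyl hydroxylase, fell 2.94-fold (log2 change -1.55, SE 0.19), Sting1, the adaptor of cytosolic DNA sensing, 2.79-fold, and Prc1, a protein of the mitotic spindle midzone, 2.12-fold. Limma adjusted p over these brighter genes was 0.0302 for Pdpn, Cd80, Inhba, Axl, Tmem176a and Egln3, 0.0175 for Timp1, 0.0310 for Tmem176b, 0.0427 for Sting1 and 0.0427 for Prc1. Of the 50 genes, 38 also passed after quantile normalization, 28 after centring and 21 after cyclic loess. Of the genes named here, Sting1 and Prc1 did not pass after centring, and Pdpn, Egln3, Tmem176b, Sting1 and Prc1 did not after cyclic loess. Whichever array was left out, 3 of the 50 passed, namely Il17f, Ccr6 and S100a6, so each gene named above lost its call without at least 1 array.

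The lower TH17 cytokine and receptor genes could come from a trend of the change with brightness, from 1 array far from its replicate or from fewer T cells in the JQ1 samples. A trend is argued against by the list's shift of -1.37 after cyclic loess, and a single array by the highest shift of -1.36 with any 1 array left out. A lower share of T cells would lower T cell genes alike, while the median of the T cell identity list was -0.16. A change of transcription in the T cells with JQ1 may be the source, as a hypothesis found and tested on the same data. A lower share of TH17 cells among the T cells, or a delay in their maturation, stays open and was not tested.

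The excess of lower over higher genes may come from an offset between the arrays, since after centring 54.3% of the genes at an unadjusted p below 0.05 were lower (95% exact binomial interval 51.5% to 57.1%, genes taken as independent), against 82.8% as deposited. Centring cannot separate an offset from a true fall of most transcripts. With every row fitted in limma, rows with 1 gene had a median change of -0.086 (741 lower, 140 higher at an unadjusted p below 0.05). The 7317 rows without a gene name had 0.055 (313 lower, 537 higher). These opposite leans argue against 1 offset shared by all rows. An offset that differs between kinds of row or with brightness stays open. A trend with brightness stays open for the same genes, as 59.6% were lower after cyclic loess, with an interval of 57.0% to 62.3%, which without the demand on intervals would have counted for the trend. Among changes of at least 2-fold, 69.9% (62.3% to 76.9%) were lower after cyclic loess, which argues against the trend as the whole cause, and 60.1% (52.0% to 67.8%) after centring, which without that demand would have counted against an offset. The real split of the 4 arrays gave the most genes at an unadjusted p below 0.05 (1 of 3 splits with as many), 1483 against 608 for the highest other, and 3 splits are too few for a share under 0.05.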
